A study of Mus musculus with 4 samples.

How the data were processed

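RNA was extracted with Trizol from the distal colon of male C57BL/6 mice aged 8 weeks that had received 1.5% dextran sulfate sodium (DSS), a polysaccharide that injures the colonic epithelium and causes colitis, for 7 days, per the labels. There were 4 libraries, 2 labelled wild type (WT) and 2 labelled Otud1-/-. The titles number the libraries 1 and 2 within each genotype. The labels do not say that each library came from its own animal, so the p-values measure only the spread between these libraries, which may be technical.

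The deposited table holds 21089 genes by versioned Ensembl identifier and 1 column per library. Its values are a normalised signal: read counts that the authors divided by 1 size factor per library, as tested on the file itself. In each library 100% of the values were whole multiples, within 0.001 of a read, of the value of 1 read. The size factors recovered in this way were 0.956 and 1.07 in WT replicates 1 and 2 and 1.03 and 0.946 in labelled Otud1-/- replicates 1 and 2. Median-of-ratios factors computed from the recovered reads were the same numbers. The smallest number of reads that any deposited gene had over the 4 libraries was 10. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the strandedness are not given in the sources used here. Without strand, reads of a gene and an antisense partner cannot be told apart.

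The recovered reads summed to 15421517 and 16730939 in WT replicates 1 and 2 and to 17215844 and 20451844 in labelled Otud1-/- replicates 1 and 2. Symbols were taken from a table of gene identifiers and matched 21043 of the 21089 genes. Positions came from GENCODE M21 on GRCm38, the assembly also called mm10. They were matched by identifier without its version, because the deposited file has no coordinates of its own.

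Because the deposited values are normalised, the main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with an intensity trend and robust variance, over the 21066 genes with a value of at least 1 in at least 2 libraries. The design fixed before the data were examined named edgeR for raw counts and this limma test for RPKM, FPKM, TPM or CPM. Counts divided by size factors are neither, and were treated as normalised values because they are not raw counts. Fold changes are labelled Otud1-/- minus WT on the log2(value + 1) scale, which understates the change of genes with low values. Adjustment was by Benjamini-Hochberg, with a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, so single genes rest on the model across genes. Intervals and floors from reads cover counting error only. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, 17587 genes after its expression filter), limma-voom and DESeq2 1.42.0. Running them on recovered reads was decided after the data were seen.

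The gene lists, 39 in number with 834 distinct members, and the rule for named genes were fixed before the data were examined. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list moves on balance in one direction without comparing it with other genes. Adjusted p-values were computed over the 39 lists. A list is described by the mean log2 difference of its measured members. Genes named in the text are Otud1, the 10 genes with the smallest unadjusted p in each direction (because fewer than 5 passed the threshold) and up to 2 members of each list with the smallest unadjusted p. The rule for the 10 also required a mean value of at least 1, no predicted-gene symbol and libraries of the 2 groups that do not overlap. Immunoglobulin and T cell receptor segments were not named singly. A gene that the rule named is not reported here. Further genes are named as chosen after their values were seen.

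The functions were tested on simulated counts with the means, library sizes and dispersions of these libraries. Genes were drawn independently and no library was made to stand apart, as labelled Otud1-/- replicate 2 did. The simulated rates therefore need not hold for the real libraries. For the comparison of labelled Otud1-/- with WT, limma called 87% of 100 genes simulated with a 16-fold change and 29% of 100 with a 4-fold change, with 10 unchanged genes called among 20562. edgeR called 86% and 27% with 10 unchanged genes called among 17607. DESeq2 called 97% and 77% with 74 unchanged genes called among 20568. A simulated list of 20 genes, among 20562, was shifted by 1 log2 unit. Its camera adjusted p was 3.6e-13 with the preset correlation and 0.59 with an estimated one. With the preset correlation 0 of 38 unchanged lists were called. Their genes varied independently, so this does not test the preset correlation on the real lists. There the estimated correlation reached 0.97, in the smooth muscle list.

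Alternatives were quantile normalisation, limma without trend and robust variance, no filter, a mean value of at least 5, a pseudocount of 0.1, the replicate number as a block, the block with a correction for GC content and length, leaving out each library, and stricter thresholds. Alternatives leaving 1 library in a group assume that it varies as the libraries of the other group do.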

Results

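The transcriptome of the distal colon was compared between WT mice and mice labelled Otud1-/-, all given 1.5% DSS for 7 days. Otud1 encodes a deubiquitinase of the ovarian tumour (OTU) family. There were 2 libraries of each genotype, with 15421517 to 20451844 reads per library, and no library without DSS. The comparison therefore addresses how the genotypes differed during colitis, not the response to DSS. Between 20498 and 20897 of the 21089 genes had at least 1 read in a library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 4 libraries, the lowest value being 285.6 normalised reads for Uty in WT replicate 1, and the labels call the mice male.

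The targeted gene was examined first. Otud1 (ENSMUSG00000043415.5) has a single exon at chromosome 2, 19657752 to 19660583, plus strand, GRCm38. Its normalised read count was 190.4 and 141.3 in WT replicates 1 and 2, and 500.4 and 253.8 in the libraries labelled Otud1-/-. The mean was thus 165.8 ± 34.7 (SD, n = 2) in WT and 377.1 ± 174.4 (SD, n = 2) in the libraries labelled Otud1-/-. The log2 difference was 1.11 with a standard error of 0.42, and limma's adjusted p was 0.45. The count went against the label, as both libraries labelled Otud1-/- had more Otud1 reads than either WT library. The part of the gene altered in the knockout is not given in the sources used here. Reads summed over the whole exon therefore do not check the label if the altered allele is still transcribed. For this reason the second group is called "labelled Otud1-/-" throughout, and every direction below rests on that label.

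In the libraries labelled Otud1-/-, interferon-stimulated and MHC class II genes stood higher, and neutrophil, red cell, NF-kB target and inflammatory cytokine genes stood lower than in WT. These statements rest on camera with a preset correlation, which called 25 of 39 gene lists. With an estimated correlation camera called 0 of the 39, the smallest adjusted p being 0.49, and fry called 1, the red cell list. The estimated correlation was 0.91 for the type I interferon list, against the preset 0.01. It was only 0.056 for the red cell list and 0.066 for the NF-kB list, which had the same adjusted p of 0.49. A simulated list of independent genes with a real shift also failed this setting, with an adjusted p of 0.59. The lack of calls there therefore cannot be laid to correlation within the lists alone. No single gene passed limma at an adjusted p of 0.05: 0 of 21066 genes, with 2343 at an unadjusted p below 0.05 (1155 higher and 1188 lower, against 1053 expected by chance). On the recovered reads edgeR also called 0 genes, with 2075 at an unadjusted p below 0.05, whereas DESeq2 called 1031, of which 603 were higher and 428 lower. All 1031 DESeq2 calls had the same direction in limma, and 970 of them had an unadjusted limma p below 0.05. Both used the same libraries, and in 1029 of the 1031 the groups did not overlap, so the shared direction adds no support. In the simulated counts DESeq2 called 74 unchanged genes and limma 10. The count rests on the libraries labelled Otud1-/-: limma called 5907 genes without replicate 1 of that group and 249 without replicate 2.

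The libraries of 1 group were not uniformly closer to each other than to the other group. Pearson's r across genes was 0.98 between the WT libraries and 0.93 between the libraries labelled Otud1-/-. Labelled Otud1-/- replicate 1 correlated at 0.96 with WT replicate 1 and at 0.95 with WT replicate 2, and so was closer to both than to its own replicate. Labelled Otud1-/- replicate 2 correlated at 0.91 and 0.90 with them. The first principal component, with 67.1% of the variance, placed this library at 139.8 and the other 3 between -74.1 and -9.85.

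Type I interferon-stimulated genes were uniformly higher in the libraries labelled Otud1-/-. Of 32 listed genes 31 were measured, all 31 had positive differences, from 1.18 to 5.23 on the log2 scale, and all 31 passed when adjusted over the list alone, while 0 passed over all genes tested. The list mean was 8.36 and 8.29 log2 units in the WT libraries and 10.69 and 11.91 in the libraries labelled Otud1-/-, a mean difference of 2.98 (camera adjusted p = 3.7e-32, and adjusted p = 0.49 with an estimated correlation). Isg15, a ubiquitin-like modifier, had a mean of 182.1 ± 20.6 (SD, n = 2) normalised reads in WT and 4405 ± 2384 (SD, n = 2) in the libraries labelled Otud1-/-. Ifit1, an interferon-induced RNA-binding protein, had means of 266.4 and 6930. The interferon gamma and guanylate-binding list had 27 of 27 members measured, all with positive differences and all passing over the list alone, with a mean difference of 2.19 (camera adjusted p = 2.8e-26, and adjusted p = 0.49 with an estimated correlation). Socs1, a feedback inhibitor of cytokine signalling, measured 143.3 and 135.7 normalised reads in WT and 619.9 and 651.3 in the libraries labelled Otud1-/-. Irgm2, an immunity-related GTPase, had a log2 difference of 2.41. The MHC class II list stood higher with all 10 members positive, 7 of them passing over the list alone, and a mean difference of 2.32 (camera adjusted p = 4.4e-10, and adjusted p = 0.49 with an estimated correlation). Its transactivator Ciita, which is also in the interferon gamma list, and the peptide-loading chaperone H2-DMb1 had log2 differences of 3.30 and 3.03. The same 2 libraries also had less skeletal muscle and red cell RNA than WT, and replicate 2 had more epithelial and less squamous RNA.

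The 10 genes with the smallest p on the higher side, none of which passed over all genes, included 6 not yet given, of which Usp18 and Ifit2 belong to the type I interferon list. Apol10a, an apolipoprotein L gene, measured 6.28 and 1.87 normalised reads in WT and 1062 and 3161 in the libraries labelled Otud1-/- (log2 difference 8.65, SE 0.75, limma adjusted p = 0.17). Its relatives Apol9a and Apol9b had log2 differences of 5.36 and 4.90, and their near-identical sequences make the split of reads between them uncertain. Ubd, a ubiquitin-like protein induced by cytokines, had means of 232.1 in WT and 3415 in the libraries labelled Otud1-/-. Usp18, which removes Isg15 from proteins, and Ifit2 had log2 differences of 3.72 and 4.89. In all 10 the 2 groups did not overlap, which was a condition of the rule. Among all genes in the fit 47.2% did not overlap, where chance gives 33.3%.

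**Figure D1:**
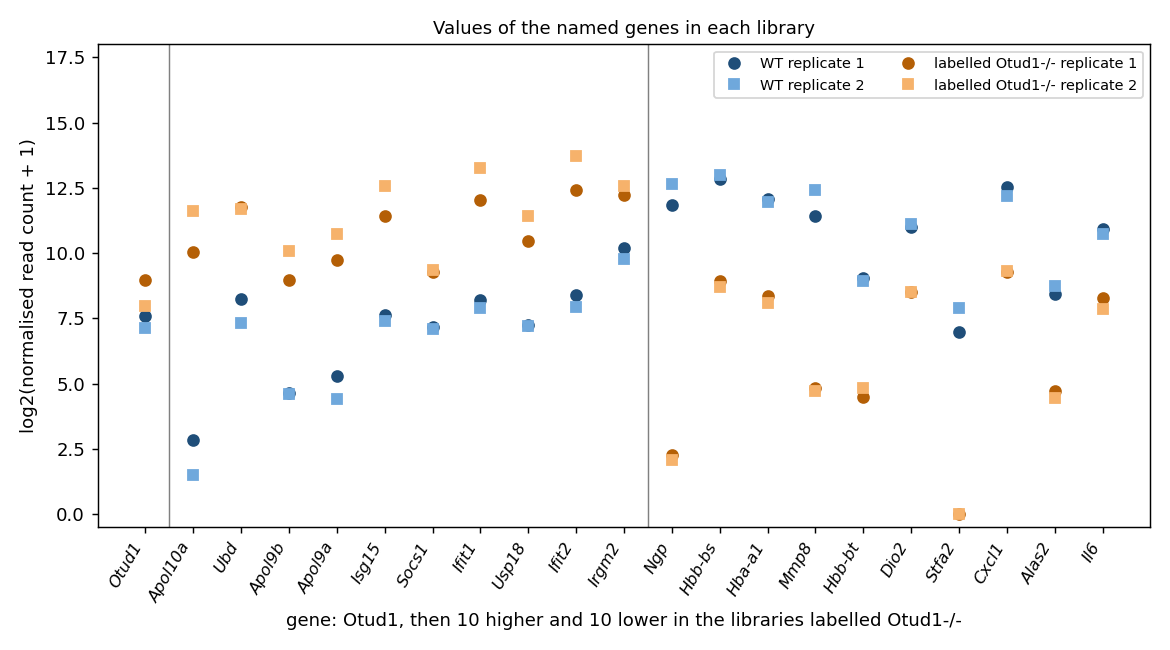
Normalised read counts on the log2(value + 1) scale (vertical axis) of Otud1 and of the 10 genes with the smallest p in each direction (horizontal axis), 1 point per library, with WT in blue and labelled Otud1-/- in orange. Otud1 was higher in both libraries labelled Otud1-/-, Ngp differed by -10.07 log2 units and Apol10a by 8.65.

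Neutrophil genes were lower in the libraries labelled Otud1-/-. Of 20 listed markers 19 were measured, 18 had negative differences, and 16 passed as lower over the list alone (0 over all genes). The list mean was 10.31 and 10.88 in the WT libraries and 7.12 and 6.20 in the libraries labelled Otud1-/-, a mean difference of -3.93 (camera adjusted p = 2.5e-19, and adjusted p = 0.49 with an estimated correlation). The red cell and skeletal muscle lists had differences of -3.62 and -4.87 in the same libraries. Ngp, a neutrophil granule protein (chromosome 9, 110419747 to 110423012), had a mean of 5043 ± 1926 (SD, n = 2) normalised reads in WT and 3.53 ± 0.50 (SD, n = 2) in the libraries labelled Otud1-/-, with the smallest p of all genes (log2 difference -10.07, SE 0.38, limma adjusted p = 0.070). Mmp8, the neutrophil collagenase, had means of 4133 and 26.3. Stfa2, a stefin, had 181.2 in WT and no reads in either library labelled Otud1-/-, at least 59.5-fold lower against a floor of 3 reads per library, although its family members are near-identical and may share reads. The calprotectin genes S100a8 and S100a9, chosen after their values were seen, had log2 differences of -5.74 and -5.28.

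The inflammatory lists were also lower as groups in the libraries labelled Otud1-/-. The NF-kB target and cytokine lists share Cxcl1, Il6, Il1b, Tnf and other members, so they are not separate results. In the same libraries the red cell, skeletal muscle and endothelial lists had differences of -3.62, -4.87 and -1.03, and labelled Otud1-/- replicate 2 stood apart, with a squamous list mean of 4.18 against 10.16 in replicate 1. Of 30 NF-kB target genes, all measured, 25 had negative differences, 15 passed as lower over the list alone and 0 as higher, with a mean difference of -0.91 (camera adjusted p = 4.4e-10, and adjusted p = 0.49 with an estimated correlation). The inflammatory cytokine and chemokine list had 41 of 42 members measured, of which 20 passed as lower and 7 as higher over the list alone, with a mean difference of -0.85 (camera adjusted p = 2.1e-06, and adjusted p = 0.49 with an estimated correlation). Cxcl1, a neutrophil chemoattractant, measured 5993 and 4640 normalised reads in WT and 628.6 and 640.8 in the libraries labelled Otud1-/- (log2 difference -3.05, SE 0.23). Il6, a pro-inflammatory cytokine, had means of 1839 ± 171 (SD, n = 2) in WT and 269.3 ± 53.4 (SD, n = 2) in the libraries labelled Otud1-/-. Genes chosen after their values were seen included Il1b with a log2 difference of -2.12, Csf3 with -4.73, Tnf with -0.35 (SE 0.31), and the interferon-inducible chemokines Cxcl9 and Cxcl10 with 2.88 and 2.77, which lie against the direction of their list. Monocyte and macrophage markers had 18 of 20 negative differences, 3 of which passed over the list alone, and a mean difference of -0.84 (camera adjusted p = 1.4e-07, and adjusted p = 0.49 with an estimated correlation). Cd14, an endotoxin co-receptor, and Cd68, a lysosomal glycoprotein, had log2 differences of -1.99 and -1.28. The metalloproteinase and tissue remodelling list had 14 of 22 members passing as lower over the list alone and a mean difference of -1.75 (camera adjusted p = 1.1e-12, and adjusted p = 0.54 with an estimated correlation). It shares Mmp8 with the neutrophil list, and Mmp9, a gelatinase, had a log2 difference of -3.93.

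Dio2, a deiodinase that activates thyroid hormone, belonged to none of these lists and was among the 10 lower genes, with 2159 ± 120 (SD, n = 2) normalised reads in WT and 365.7 ± 3.25 (SD, n = 2) in the libraries labelled Otud1-/-. The components of the TNF receptor and RIPK1 pathway did not pass as a list, with all 29 measured, a mean difference of 0.23 and a camera adjusted p of 0.18. None of the 29 passed over the list alone. The list passed without labelled Otud1-/- replicate 1 (0.39, adjusted p = 0.032), and its mean was 0.065 without replicate 2. Ripk3, a necroptosis kinase, had a log2 difference of 1.26 and Rnf31, a subunit of the linear ubiquitin ligase, 1.12, while Ripk1, chosen after its values were seen, had 0.03 (SE 0.22). The 15 measured OTU-family deubiquitinases had a mean difference of 0.09 (camera adjusted p = 0.53), with Tnfaip3 at -0.95 (SE 0.26). They include the targeted gene Otud1 itself, which had the largest positive difference of the list at 1.11.

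Colonic epithelial genes stood higher in the libraries labelled Otud1-/-, most of all in replicate 2. Between replicates 1 and 2 of that group the squamous list mean also differed, at 10.16 and 4.18, and the skeletal muscle mean was 6.66 and 3.87, against 10.55 and 9.72 in WT. The pan-epithelial list mean was 11.55 and 10.72 in the WT libraries and 11.81 and 13.37 in the libraries labelled Otud1-/- (mean difference 1.46, camera adjusted p = 2.7e-06, and adjusted p = 0.60 with an estimated correlation), with 0 of 20 passing over the list alone. Vil1, a microvillus protein, and Hnf4a, a transcription factor, both had log2 differences of 2.60, and leaving out single libraries put Hnf4a between 1.55 and 3.65. Absorptive colonocyte markers had a mean difference of 1.80 (camera adjusted p = 2.4e-08, and adjusted p = 0.60 with an estimated correlation), with 5 of 25 passing as higher and 1 as lower over the list alone. Car4, a carbonic anhydrase, and Krt20, a keratin of surface epithelium, had log2 differences of 3.25 and 2.29. Goblet cell markers had a mean difference of 1.84 (camera adjusted p = 5.8e-06, and adjusted p = 0.63 with an estimated correlation), with 0 of 22 passing over the list alone. Their list means were 9.65 and 7.97 in WT and 9.70 and 11.59 in the libraries labelled Otud1-/-. Replicate 1 of the labelled group thus lay at the level of WT replicate 1. Clca1, a secreted goblet cell protein, and Retnlb, an antibacterial one, had log2 differences of 3.59 (2.35 to 4.83 leaving out single libraries) and 4.06. Tight and adherens junction genes had a mean difference of 0.84 (camera adjusted p = 3.8e-05, and adjusted p = 0.60 with an estimated correlation), with 0 of 24 passing over the list alone. E-cadherin, Cdh1, was at 1.73 (1.004 to 2.45 leaving out single libraries) and Cldn7, a claudin, at 1.76 (1.09 to 2.43). Both genes are also in the pan-epithelial list. The antimicrobial and acute-phase list stood higher by 0.86 (camera adjusted p = 0.038, and adjusted p = 0.63 with an estimated correlation), with 15 of 23 differences positive, 1 member passing as higher and 2 as lower over the list alone. Its means were 9.68 and 8.54 in WT and 9.83 and 10.11 in the libraries labelled Otud1-/-. The members with the smallest p were those lower: Lcn2, an iron-sequestering protein, had a log2 difference of -4.29 and Saa3, an acute-phase protein, -3.76. Both are also made by cells other than epithelium. Without labelled Otud1-/- replicate 2 the goblet cell list no longer passed, with a mean difference of 0.89 and an adjusted p of 0.087. Without that library the mean difference was 0.68 for the pan-epithelial list, 0.85 for colonocytes and 0.34 for junction genes. Without labelled Otud1-/- replicate 1 these 3 were 2.24, 2.74 and 1.35, and goblet cells 2.78. Without WT replicate 2 goblet cells were at 0.997. The antimicrobial list was at 1.43 without WT replicate 1, and did not pass when WT replicate 2 (0.29, adjusted p = 0.21), labelled Otud1-/- replicate 1 (0.998, adjusted p = 0.12) or labelled Otud1-/- replicate 2 (0.72, adjusted p = 0.28) was left out.

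**Figure D2:**
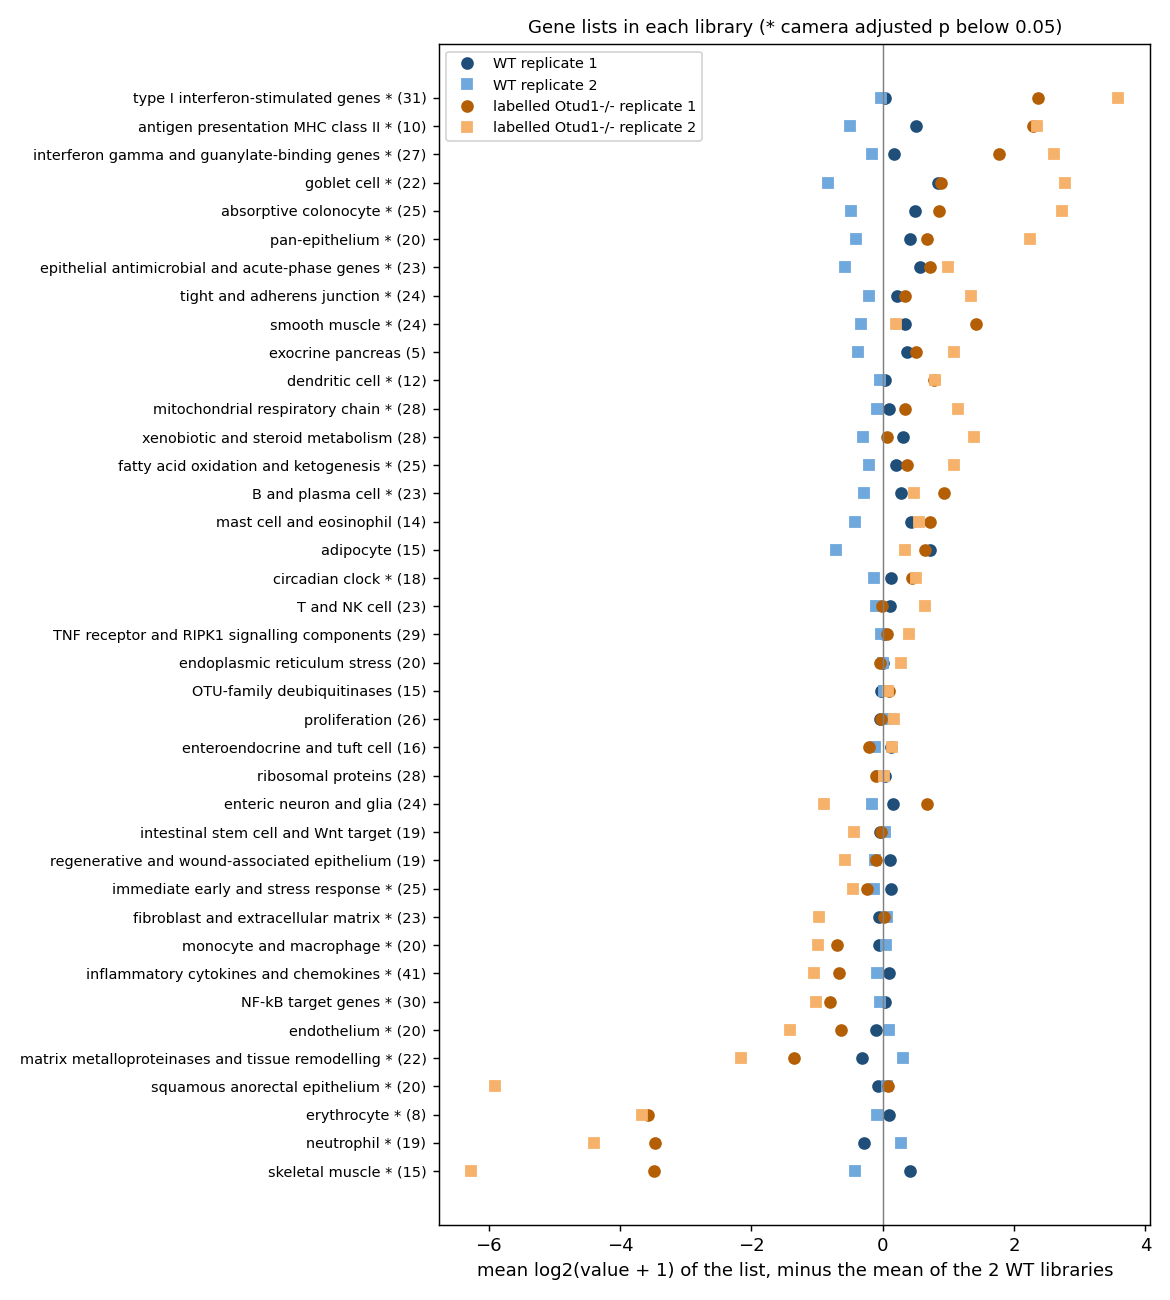
Mean log2(value + 1) of each gene list in each library, minus the mean of the 2 WT libraries (horizontal axis), for the 39 lists (vertical axis, measured members in parentheses), with WT in blue and labelled Otud1-/- in orange. Asterisks mark lists past camera with the preset correlation. Squamous genes were low in labelled Otud1-/- replicate 2 alone, and the interferon and neutrophil lists differed in both libraries of that group.

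Tissues other than colonic mucosa were unequally represented in the libraries. Skeletal muscle genes had list means of 10.55 and 9.72 in WT and 6.66 and 3.87 in the libraries labelled Otud1-/-, with all 15 measured members passing as lower over the list alone (mean difference -4.87, camera adjusted p = 1.7e-14, and adjusted p = 0.49 with an estimated correlation). Myh4, a fast myosin heavy chain, measured 177.8 and 788.7 normalised reads in WT and no reads in the libraries labelled Otud1-/-, at least 159-fold lower against a floor of 3 reads per library, or at least 58.4-fold from WT replicate 1 alone. Pvalb, a calcium-binding protein of fast muscle, had a log2 difference of -4.59. Squamous anorectal markers had list means of 10.02, 10.15 and 10.16 in WT replicates 1 and 2 and labelled Otud1-/- replicate 1, and 4.18 in labelled Otud1-/- replicate 2. Their mean difference of -2.92 (camera adjusted p = 0.0037, and adjusted p = 0.65 with an estimated correlation) came from that library and was 0.074 without it (adjusted p = 0.80), against -5.90 without labelled Otud1-/- replicate 1. Krt15, a basal keratin, had 1913, 2746, 487.7 and 15.9 normalised reads in the same order (log2 difference -4.66, and -7.09 to -2.23 leaving out single libraries), whereas Sprr2a3, a cornified envelope protein of a multigene family, had a log2 difference of 2.05. Red cell genes were lower in the libraries labelled Otud1-/-, with all 8 measured members passing over the list alone and a mean difference of -3.62 (camera adjusted p = 2.8e-13, adjusted p = 0.49 with an estimated correlation, fry adjusted p = 0.033). The haemoglobin genes Hbb-bs, Hbb-bt and Hba-a1 had log2 differences of -4.09, -4.34 and -3.81, and Alas2, the erythroid haem synthesis enzyme, -4.01. The split between the haemoglobin copies is uncertain.

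Endothelial markers were lower in the libraries labelled Otud1-/-, with 12 of 20 passing over the list alone and a mean difference of -1.03 (camera adjusted p = 1.7e-11, and adjusted p = 0.57 with an estimated correlation), among them Emcn at -1.63 and the transcription factor Erg at -1.31. The endothelial mean was -0.64 without labelled Otud1-/- replicate 2. Smooth muscle markers had a mean difference of 0.81 (camera adjusted p = 7.1e-05, and adjusted p = 0.65 with an estimated correlation), which came mainly from labelled Otud1-/- replicate 1 and was 0.20 without it (adjusted p = 0.52), 0.48 without WT replicate 2 and 1.43 without labelled Otud1-/- replicate 2. Cnn1, calponin, and Tagln, transgelin, had log2 differences of 1.75 and 1.52. Fibroblast and matrix genes had a mean difference of -0.47 (camera adjusted p = 0.0012, and adjusted p = 0.65 with an estimated correlation), which came from labelled Otud1-/- replicate 2 and was 0.020 without it (adjusted p = 0.82) and -0.96 without labelled Otud1-/- replicate 1. Pdgfrb and Pdpn had log2 differences of -1.43 and -0.99. Enteric neuron and glia, adipocyte and exocrine pancreas lists did not pass, with mean differences of -0.11, 0.49 and 0.79 and camera adjusted p of 0.54, 0.72 and 0.35. The enteric neuron and glia list passed in opposite directions when labelled Otud1-/- replicate 1 (-0.90, adjusted p = 2.0e-05) or replicate 2 (0.68, adjusted p = 7.2e-07) was left out, and the adipocyte list passed without WT replicate 1 (1.21, adjusted p = 0.0055) but was at -0.22 without WT replicate 2. The pancreas list lay between 0.42 and 1.17 when single libraries were left out. The members with the smallest p were Gfra3 and Tac1 at -0.72 and 0.60, Fabp4 and Acvr1c at -0.93 and 2.63, and Clps and Ctrl at 3.24 and 1.03, respectively. Leaving out single libraries put Tac1 between 0.14 and 1.06, Fabp4 between -1.28 and -0.58, Acvr1c between 1.46 and 3.80 and Clps between 1.69 and 4.80.

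Transcripts of the mitochondrial genome took 2.134% and 1.998% of the reads in WT and 2.653% and 2.913% in the libraries labelled Otud1-/-. Mean log2 values of the respiratory chain list were 11.01 and 10.83 in WT and 11.26 and 12.07 in the libraries labelled Otud1-/-, against 11.55, 10.72, 11.81 and 13.37 for the pan-epithelial list in the same order. The mitochondrial respiratory chain list had 27 of 28 positive differences and a mean of 0.75 (camera adjusted p = 3.1e-09, and adjusted p = 0.60 with an estimated correlation), with Ndufa1 and Ndufb8, both complex I subunits, at 0.89 and 0.90 (0.54 to 1.27 for Ndufb8 leaving out single libraries). The fatty acid oxidation and ketogenesis list had 22 of 25 positive differences and a mean of 0.72 (camera adjusted p = 2.4e-05, and adjusted p = 0.60 with an estimated correlation), with Acadl and Slc25a20 at 1.35 and 1.74. In both lists 0 members passed over the list alone. Without labelled Otud1-/- replicate 2 their means were 0.34 and 0.36, and the respiratory chain was at 1.15 without labelled Otud1-/- replicate 1. Immediate early and stress response genes had a mean difference of -0.34 (camera adjusted p = 0.0087, and adjusted p = 0.54 with an estimated correlation), with 5 of 25 passing as lower over the list alone, but were at -0.22 and did not pass without WT replicate 1 (adjusted p = 0.10). Dusp1, a MAP kinase phosphatase, had a log2 difference of -1.94 and Ier3 -1.58.

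Several lists did not pass camera, some of which passed under another setting. Proliferation genes had a mean difference of 0.08 and a median of -0.0069 (adjusted p = 0.72), with Rrm2 at -0.64 (-1.01 to -0.27 leaving out single libraries) and Ube2c at 0.68 (0.30 to 1.06). Intestinal stem cell and Wnt target genes had a mean difference of -0.24 (adjusted p = 0.72; -0.44 to -0.034 leaving out single libraries). Their member Olfm4 measured 54.4 and 144.1 normalised reads in WT and no reads in the libraries labelled Otud1-/-, at least 32.6-fold lower against a floor of 3 reads per library (17.9-fold from WT replicate 1 alone), and Ephb2 had a log2 difference of 1.38 (0.84 to 1.92 leaving out single libraries). Olfm4 was the only member passing over the list alone, so it does not speak for stem cell genes as a group. Which cells it came from was not tested. The regenerative epithelium list had a mean difference of -0.34 (adjusted p = 0.19), with Itgb6, an integrin, passing as higher over the list alone at 2.09 and Plaur, the urokinase receptor, passing as lower at -1.61. This list passed after quantile normalisation (-0.51, adjusted p = 0.041), and leaving out single libraries put it between -0.57 and -0.10. Xenobiotic metabolism had a mean difference of 0.73 (adjusted p = 0.19), with Cyp2f2 at -1.49 and Gsta4 at -1.50. The xenobiotic list passed without WT replicate 1 (1.03, adjusted p = 0.015) or labelled Otud1-/- replicate 1 (1.39, adjusted p = 0.012), and its mean was 0.065 without labelled Otud1-/- replicate 2. Enteroendocrine and tuft cell markers had -0.03 (adjusted p = 0.59), with Il17rb at 1.44 and Cck at -0.73. Endoplasmic reticulum stress had 0.11 (adjusted p = 0.83), with Trib3 at -1.30 (-1.80 to -0.79 leaving out single libraries) and Ern2 at 2.44 (1.19 to 3.69). Ribosomal proteins had -0.04 (adjusted p = 0.59), with Rps18 at -0.12 (-0.17 to -0.076 leaving out single libraries), but passed as lower after quantile normalisation (-0.36, adjusted p = 3.3e-05).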

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

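The tests on recovered reads were chosen after the data were seen, and all other alternatives before. The limma count of 0 genes at an adjusted p of 0.05 was also 0 without trend and robust variance, without a filter, with a mean value of at least 5, with a pseudocount of 0.1, at the stricter thresholds, and on the recovered reads with limma-voom and with edgeR (TMM, RLE or without robust estimation). Quantile normalisation called 3 lower genes (Ngp, Hbb-bs and Hba-a1). The replicate block called 1 lower gene (Ngp) and ended no list call, and the block with the GC and length correction 2 (Ngp and Mmp8). The numbers share no stated litter or day, and the difference between replicates 1 and 2 correlated across genes at -0.04 between the groups, so they were not read as pairs. DESeq2 called 1031 genes, 603 higher and 428 lower. Leaving out each library gave 0 to 5907 genes, with 0 to 2993 higher and 0 to 2914 lower. The highest counts came without labelled Otud1-/- replicate 1, when the lone library is assumed to vary as the WT libraries do, and 249 came without labelled Otud1-/- replicate 2 (98 higher, 151 lower). Otud1 stayed higher under all alternatives run, from 0.63 to 1.60, with no adjusted p under 0.066. No library size correction moved the median of all genes by over 0.1. Camera with the preset correlation called 14 lists higher and 11 lower. Of these 25, 16 (8 higher and 8 lower) kept the call in all 16 settings with that set test, which was not run for DESeq2. With an estimated correlation 0 and 0 were called, and with fry 0 higher and 1 lower (red cells). A simulated list with a real shift was not called with an estimated correlation either. For the named genes that are reported, 0 of 1328 values under alternatives changed sign. In these genes, as in Otud1, the groups did not overlap, so leaving out a library could not reverse a sign. However, 17 of the 83 fold changes other than that of Otud1 moved by over 1.5 times when a library was left out. Of the 14 lists not called, 8 passed in at least 1 other setting: mast cells and eosinophils, regenerative epithelium, ribosomal proteins, adipocytes, xenobiotic metabolism, T and NK cells, enteric neurons and glia, and TNF receptor and RIPK1 components. Lists that changed sign had not passed, apart from the fibroblast and squamous lists. Leaving out single libraries gave means from -0.20 to 0.14 for enteroendocrine and tuft cells, -0.90 to 0.68 for enteric neurons and glia, -0.22 to 1.21 for adipocytes, -0.10 to 0.019 for ribosomal proteins, -0.0083 to 0.64 for T and NK cells, -0.022 to 0.18 for proliferation, -0.96 to 0.020 for fibroblasts, -5.90 to 0.074 for squamous epithelium and -0.049 to 0.27 for endoplasmic reticulum stress. The last was -0.046 after quantile normalisation, enteroendocrine and tuft cells 0.068 with a pseudocount of 0.1, and enteric neurons and glia 0.074 in edgeR with or without robust estimation and 0.12 with RLE factors. The squamous mean was -0.81 in edgeR and the fibroblast mean -0.74 after quantile normalisation. The antimicrobial list also lost its call with the block and GC and length correction (0.85, adjusted p = 0.052) and in edgeR with RLE factors (0.87, adjusted p = 0.057), with means close to the 0.86 of the main test. The cause was not tested.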

Other observations

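Markers of further immune populations were examined in the same way. Among mast cell and eosinophil markers, which as a list did not pass (mean difference 0.64, camera adjusted p = 0.063), the mucosal mast cell proteases Mcpt1 and Mcpt2 passed over the list alone, with log2 differences of 2.73 and 2.38 in the libraries labelled Otud1-/-. This list passed in 5 of the 16 settings, among them quantile normalisation (0.71, adjusted p = 0.023) and without WT replicate 1 (1.06), and its mean was 0.21 without WT replicate 2. Dendritic cell markers stood higher by 0.79 (camera adjusted p = 0.0078, and adjusted p = 0.49 with an estimated correlation). Xcr1, a chemokine receptor of cross-presenting dendritic cells, measured 4.18 and 3.74 normalised reads in WT and 43.7 and 74.0 in the libraries labelled Otud1-/-, and Cd209a had a log2 difference of 2.72. The dendritic list did not pass when either of the libraries labelled Otud1-/- was left out (highest adjusted p = 0.081), although its mean was then 0.79 or 0.78. B and plasma cell markers stood higher by 0.70 (camera adjusted p = 0.0075, and adjusted p = 0.57 with an estimated correlation), but did not pass without labelled Otud1-/- replicate 1 (0.47, adjusted p = 0.092), and were at 0.42 without WT replicate 2. None of their members passed over the list alone, with Sdc1 at -1.05 and Cr2 at 2.71. T and NK cell markers had a mean difference of 0.32 (camera adjusted p = 0.18), with Ctla4 at -0.98 and Cd8a at 1.75 (0.92 to 2.58 leaving out single libraries). This list passed without labelled Otud1-/- replicate 1 (0.64, adjusted p = 0.019) and was at -0.0083 without replicate 2.

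All tests in the rest of this section were chosen after the results were seen, except the clock test. The first pattern is that Otud1 was higher in the libraries labelled Otud1-/-. The annotation lists 0 other genes overlapping Otud1, which argues against reads of an overlapping gene. The ratio of means was 2.27, and neither group lay at or below 0.1 times the other. These counts therefore do not separate a swap of the 2 genotype labels from correct labels. The libraries labelled WT held 182 and 151 reads of Otud1. Under a swap, too, the altered allele would have to give reads in the exon, so a swap alone would not account for the counts. The share of smooth muscle in the piece stays open: relative to the smooth muscle list the groups differed by 0.30 log2 units, with 0.18 of a difference of 1.60 remaining in labelled Otud1-/- replicate 1 but 0.43 of 0.63 in replicate 2. Reads along the exon were not analysed here.

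The second pattern is lower neutrophil genes with higher interferon-stimulated genes in the libraries labelled Otud1-/-. Dilution of colon RNA by other tissue in WT would move interferon-stimulated and epithelial genes alike, if that tissue held little of either. Relative to the pan-epithelial list, the interferon-stimulated list differed between groups by 1.52 log2 units (SE 0.42). This goes against an equal move, but 2 libraries per group are too few to exclude dilution for the interferon-stimulated genes. Dilution by tissue with few neutrophils would also lower neutrophil genes in WT. Their list means were instead higher there, at 10.31 and 10.88 against 7.12 and 6.20 in the libraries labelled Otud1-/-. For the neutrophil genes this argues against such dilution. Squamous anorectal tissue stays open: labelled Otud1-/- replicate 1, with squamous genes at the WT level, still had neutrophil genes at -3.47 against WT, but this is 1 library. More blood in the WT pieces remains possible for the neutrophil and red cell genes, whose mean differences lay within 0.32 of each other. Close means cannot decide this: members ran from -10.07 to 0.63 in the neutrophil list and -4.77 to -1.75 in the red cell list. In WT, moreover, the haemoglobin gene Hbb-bs averaged 7755 normalised reads and the neutrophil gene S100a9 19609. Genotype and severity of colitis in single animals stay open, as untested.

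The third pattern concerns the circadian clock list, which stood higher by 0.48 (camera adjusted p = 0.0063, and adjusted p = 0.51 with an estimated correlation) but did not pass without labelled Otud1-/- replicate 2, with a mean of 0.45 (adjusted p = 0.057). Dbp, a clock-controlled transcription factor, had 355.6 and 221.7 normalised reads in WT and 1600 and 1163 in the libraries labelled Otud1-/-, and Nr1d1, a clock repressor, had a log2 difference of 1.67. A hypothesis is that the groups were collected at other times of day, which would lower Arntl, Npas2 and Clock, genes of the opposite phase. Their mean difference was 0.20 with a standard error of 0.53, too imprecise to decide, because the libraries labelled Otud1-/- lay on both sides of WT.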
